A study of Homo sapiens with 2 samples.

How the data were processed

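Single-cell RNA sequencing was compared between 2 libraries of human induced pluripotent stem cells of the ICSIG-1 Sigma line. In the RACL library, naive cells had been converted for 6 days in RPMI medium with B27 lacking insulin, activin A (100 ng/mL), the GSK3 inhibitor CHIR99021 (3 µM) and LIF (10 ng/mL). The NACL library was taken at day 24, after transfer to N2B27 medium with the same 3 factors at the same doses and the ROCK inhibitor Y-27632 (10 µM). Both cultures grew on mouse feeder cells under hypoxia, per the labels' protocols. Droplet libraries of the 3' v3.1 chemistry were loaded for 2000 cells, per the labels. The protocol text also describes a mixture of trophoblast stem cells with naive and primed cells, and whether it applies to these libraries is not stated.

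The authors deposited a table of raw UMI counts for 24907 gene symbols in 668 cells, and an annotation table that assigns each cell to a library and to a named class. The UMI counts and genes per cell that the authors deposited in the annotation equalled the sums over the count table in all 668 cells. Per the submitters' processing notes, Cell Ranger 4.0.0, Seurat 4.0.1 and FastQC were used, and the builds GRCh38, hg38 and mm10 are named without a role. The deposited cells held 201 to 7998 genes and at most 19.9% mitochondrially encoded UMIs, so cells outside limits near these values had been removed. The table held no mouse gene symbols. All 668 barcodes carry the suffix 1, and how barcodes were assigned to a library is not given in the sources used here. Gene identifiers and coordinates were taken from GENCODE release 29 (GRCh38) by symbol, which matched 23035 symbols.

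Cell classes were the authors' own: EXMC (extraembryonic mesoderm cells), PrE (primitive endoderm) and intermediate 1, 2 and 3. The annotation writes each name with a library prefix, which was dropped here. In 10 cells that the annotation assigns to the NACL library, the name is RACL.intermediate.3, and these were kept in the NACL library. Counts were summed over the cells of a class and library and scaled to the class's total count as CPM. Intervals were exact Poisson for a level, exact conditional binomial for a ratio of levels and exact Clopper-Pearson for a share, all at 95%. They cover counting error only. Each group had 1 library, so no test between conditions was possible, no p-value is given, and cells were not used as replicates. A gene is called higher or lower only by size, when its CPM differed at least 2-fold and the counting interval of the ratio excluded 1. Against 0 counts, the floor was 3 counts per class and library, and the fold is a lower bound. For a share of 0, the limit is likewise that of 3 cells. These floors are a convention, and the exact 95% limits are wider.

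Lists of 11 cell-type marker sets and 20 pathway sets were fixed before the data were examined, with 385 of their 386 genes in the table. A member counted as measured at 10 CPM or more in either group. The list value is the median difference of log2(CPM + 5). Its percentile was taken among 10000 random lists of the same size, matched on mean expression over 20 bins, and describes these libraries only. The named genes of the EXMC comparison were the 12 with the largest and the 12 with the smallest log2 difference. They had to reach 50 CPM in the higher library, detection in at least 10% of its cells of the class, and a 2-fold difference. Mitochondrially encoded, ribosomal protein, clone-named, mouse and sex-linked marker genes were left out. For each list, up to 4 members with the largest differences are also named, and all members where 5 or fewer were measured. In the comparison of classes, up to 6 members per marker list with the highest levels are named. A few other members are named as exceptions to their list, and these were chosen after their values were seen.

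The size rule was tested on simulated counts for the EXMC comparison over 8694 genes, of which 200 were changed. It recovered 50 of 50 genes raised 4-fold, 50 of 50 lowered 4-fold, 4 of 50 raised 1.5-fold and 1 of 50 lowered by the same ratio. It called 28 of 8494 unchanged genes, and 95.9% of the ratio intervals covered the simulated value. The simulated counts held counting error only, which is the error the intervals are built for, so this coverage was set by the design. Spread between cells or cultures was not simulated. The calls among unchanged genes are therefore no false-call rate for the comparison of the real libraries.

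Alternatives were TMM scaling (edgeR 4.0.16), DESeq2 1.42.0 size factors, totals without mitochondrial and ribosomal protein genes, the mean of per-cell CPM, a pseudocount of 1, no filter on low values, removal of doublet calls, stricter cell limits (at least 1000 genes and under 20% mitochondrial) and rebuilt classes. Of the cell limits, the mitochondrial one removed no cell, since the deposited cells held at most 19.9%, so only the gene limit acted. Doublets were called with Scrublet in scanpy 1.11.5 on 15 components. It called 10 of 75 NACL cells and 0 of 593 RACL cells. Classes were rebuilt per library by Leiden clustering at resolution 1 on 2000 variable genes, 15 components and 15 neighbours, and named by the fixed markers. For shares of cells with a UMI, cells were thinned to 10000 UMIs, and cells below that were left out. Analyses ran in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9) and R 4.3.3.

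The planned comparison of endoderm cells between libraries was not made, because the annotation holds 0 endoderm cells in the NACL library. The comparison of EXMC with endoderm was therefore made in the RACL library alone. Results for some single members of the gene lists are not reported here.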

Results

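The data comprised 668 cells, 593 from the RACL library at day 6 and 75 from the NACL library at day 24. The RACL library held 13155066 UMIs with a median of 16598 per cell, and the NACL library 2066254 UMIs with a median of 26955. Each condition had 1 library, and day and medium differed together between them. All intervals below are 95% counting intervals, which do not include the spread between cultures.

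The question of the class shares was which cell types each culture contained. The NACL library consisted mainly of EXMC cells, which were 65 of 75 cells (86.7%, 76.8 to 93.4). In the RACL library EXMC cells were 67 of 593 (11.3%, 8.86 to 14.1) and PrE cells, labelled as primitive endoderm, were 55 (9.27%, 7.06 to 11.9). The NACL library held 0 PrE cells, which allows a share of up to 4% by the limit of 3 cells, or 4.80% by the exact interval. The rest of the RACL library was intermediate 1 (156 cells, 26.3%), intermediate 2 (63 cells, 10.6%) and intermediate 3 (252 cells, 42.5%). The rest of the NACL library was 10 intermediate 3 barcodes (13.3%, 6.58 to 23.2), whose class name in the annotation carries the prefix RACL. Intermediate 3 was shallow in both, with a median of 890 UMIs in RACL and 406.5 in NACL, against 39398 and 28925 in the EXMC classes. These shares therefore depend on how many shallow barcodes are kept. With barcodes of at least 1000 genes and under 20% mitochondrial UMIs, EXMC made up 16.3% of RACL cells and 100% of NACL cells, and PrE made up 14.0% of RACL cells. With rebuilt clusters named by the fixed markers, no RACL cluster was named endoderm-like, so the PrE share was 0%. Each cluster took only the name of its best-scoring list. The cluster with 33 of the 55 PrE cells was named primitive streak-like, and its top genes included the endoderm markers CER1 and SOX17. The 0% therefore does not show that endoderm-type cells were absent.

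**Figure D1:**
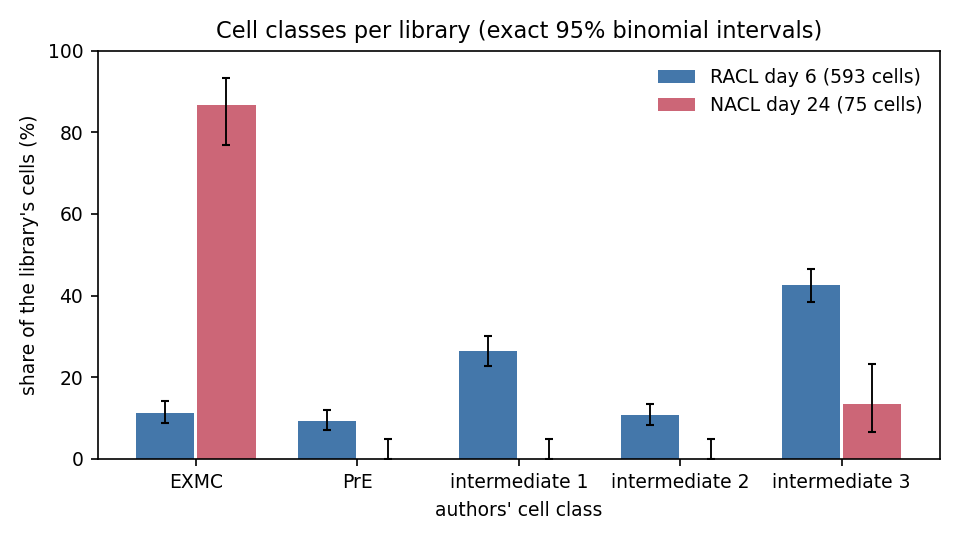
Share of each library's cells (vertical axis, percent) in each of the authors' classes (horizontal axis). Blue bars are the RACL library at day 6 and red bars the NACL library at day 24, with exact 95% binomial intervals. EXMC reached 86.7% in NACL against 11.3% in RACL.

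Of the 18 endoderm markers, 9 had 0 UMIs in the 75 cells of the day 24 library, 7 had 1 to 8 UMIs and 2 had more. SOX17 and FOXA2, transcription factors of endoderm, were among those at 0, as were APOB, AFP and OTX2. CER1, a secreted inhibitor of nodal and BMP signalling, had 6 UMIs in 5 cells. The 2 markers with more were FLRT3, with 89 UMIs in 32 cells, and PRDM1, with 42 UMIs in 18 cells. In the RACL library SOX17 UMIs were found in 43.6% of PrE cells (30.3 to 57.7) at a median of 37580 UMIs. The share was 0.641% in intermediate 1 cells, which served as background, at a median of 43673.5 UMIs. In the 52 PrE cells with at least 10000 UMIs the share was 44.2%, and 26.9% after thinning.

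The comparison of EXMC cells asked how the cells given this name differed between day 24 in NACL and day 6 in RACL. Genes of the fibrillar extracellular matrix were higher at day 24 throughout the list, in 17 of 17 measured members, with a median log2 difference of 3.08. LUM, a small proteoglycan that binds collagen fibrils, reached 3005 CPM against 4.01 (749.7-fold higher, 407 to 1564). DCN, a proteoglycan of the same family, reached 1556 CPM against 0 counts, at least 1294-fold higher by the floor (exact lower limit 1052). MGP, an inhibitor of calcification, was 296-fold higher (127 to 914; 451-fold with the mean of per-cell CPM), and COL1A1, a chain of type I collagen, was at 4607 CPM against 67.3 (68.4-fold, 58.7 to 80.2). The most abundant member, COL3A1, was already present at day 6 at 806 CPM and was 12.9-fold higher at day 24 (12.3 to 13.5). These genes took 3.07% of all EXMC UMIs in NACL (3.051 to 3.098) and 0.251% in RACL (0.244 to 0.257). The list median lay above those of nearly all random lists (percentile 100). The annotation writes the 2 classes as NACL.EXMC and RACL.EXMC.

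**Figure D2:**
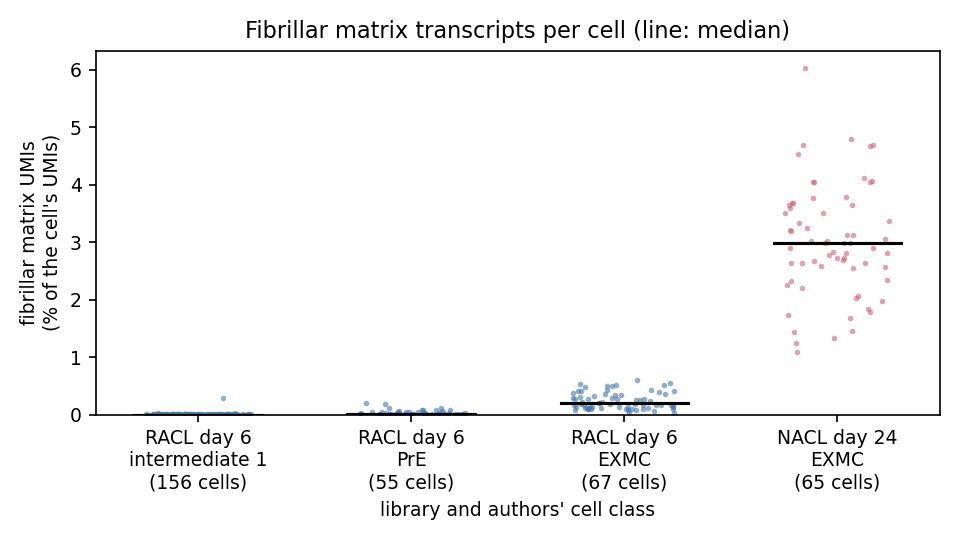
Fibrillar matrix UMIs as a percent of each cell's UMIs (vertical axis) in 4 classes (horizontal axis). Each point is a cell and each line a class median. The median was 2.98% in NACL EXMC and 0.200% in RACL EXMC.

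Among the other named genes higher at day 24, AHR, the aryl hydrocarbon receptor, was at 329 CPM against 1 count, a ratio of 822 (147 to 32519), or 424 with rebuilt clusters, and SEMA3C was at 277 CPM against 2 counts, a ratio of 345 (95.1 to 2856). IGFBP5, a binding protein of insulin-like growth factors, was at 4169 CPM against 27.7 (151-fold, 119 to 194), and IGFBP7 was 116-fold higher (55.9 to 289). SPOCK1 was 136-fold higher (73.5 to 284), SULF1, an extracellular heparan sulfatase, was 122-fold higher (75.1 to 214), OGN was 109-fold higher (58.8 to 228) and COL15A1 was 64.6-fold higher (44.5 to 97.6).

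Of the 12 named genes lower at day 24, ACTC1, the cardiac alpha actin, was at 4.37 CPM against 1468 (336-fold lower, 177 to 736; 537-fold with the mean of per-cell CPM). NPPB, which encodes the natriuretic peptide BNP, had 0 counts against 372 CPM, at least 255-fold lower. LIN28A, an RNA-binding protein of pluripotent and early embryonic cells, had 0 counts against 359 CPM, at least 246-fold lower. HAND1, a mesodermal transcription factor, had 0 counts against 162 CPM, at least 111-fold lower. The keratin genes among the 12 were KRT18, lower by a factor of 30.3 (24.4 to 38.04), KRT19 by 32.4 (23.3 to 46.5) and KRT8 by 25.2 (19.1 to 33.9). PDPN was 157-fold lower (61.0 to 577) and RSPO2, an enhancer of WNT signalling, was 40.9-fold lower (23.7 to 77.1). LIX1 was 31.8-fold lower (19.1 to 57.1), with a log2 difference of -4.27, or -3.25 with the mean of per-cell CPM. PODXL had 2 counts at day 24, a ratio of 191 (52.6 to 1584), and APLNR also had 2 counts, a ratio of 137 (37.7 to 1137), 209 with the mean of per-cell CPM and 227 without doublet calls.

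In GENCODE release 29 (GRCh38), LUM (ENSG00000139329) lies on chromosome 12 at 91102629 to 91111831 and DCN (ENSG00000011465) on the same chromosome at 91140484 to 91183123. COL1A1 (ENSG00000108821) lies on chromosome 17 at 50183289 to 50201632. ACTC1 (ENSG00000159251) lies on chromosome 15 at 34788095 to 34795726, NPPB (ENSG00000120937) on chromosome 1 at 11857464 to 11858931 and HAND1 (ENSG00000113196) on chromosome 5 at 154474972 to 154478264. All 6 are protein-coding genes, and a droplet count covers the whole gene, with reads near its 3' end.

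Markers of extraembryonic mesoderm as a list were higher in 13 and lower in 2 of 19 measured members (median log2 difference 1.87). This list shares several members with the fibrillar list. Among the others, HGF was 27.7-fold higher (18.8 to 42.3) and TWIST1 was 13.0-fold higher (10.7 to 16.0), while HAND1 and NID2 were lower. Mesenchymal genes were split, with 8 higher and 4 lower of 18 (median 0.52). ZEB1, a repressor of epithelial genes, was 49.6-fold higher (29.3 to 91.4) and VIM was 5.65-fold higher (5.49 to 5.82), whereas ZEB2 and TAGLN were lower. Epithelial genes had 3 lower of 4 measured members of 14 (median -4.54), and the median was -0.51 without the filter on low values. Basement membrane genes had 3 higher and 3 lower of 13 (median 0.45): SPARC was 4.33-fold higher (4.11 to 4.57), and COL18A1 was at 76.7 against 437 CPM.

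Genes of cholesterol synthesis were lower at day 24 in 12 of 16 members and higher in 0 (median -1.35, percentile 0). HMGCS1 was at 49.0 against 227 CPM, SQLE at 109 against 425 and FDFT1 at 43.7 against 155. Proliferation genes were lower in 8 of 20 and higher in 0 (median -0.81); with the mean of per-cell CPM, 14 were at least 2-fold lower. The lower members included the replication licensing genes MCM2 (6.79 against 43.3 CPM), MCM3 (37.4 against 187) and MCM5 (15.5 against 48.5), while MKI67 was at 282 against 163 CPM and did not reach 2-fold. Hypoxia target genes had 6 lower and 1 higher of 14 (median -0.54). The lower ones included the glycolytic genes ENO1 (450.3 against 1349 CPM) and LDHA (209.6 against 630.4) and the glucose transporters SLC2A1 and SLC2A3.

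Imprinted genes had 5 higher and 3 lower of 11 (median 0.54). MEG3 was 16.1-fold higher (13.9 to 18.8), KCNQ1OT1 was 12.1-fold higher (10.7 to 13.7) and H19 was 4.85-fold higher (4.58 to 5.13). Interferon response genes had 4 higher and 0 lower of 9 (median 0.76), led by B2M, the light chain of HLA class I, at 7.94-fold (6.64 to 9.55). HLA-B was also higher, and reads of HLA genes can be shared between paralogs. Core pluripotency genes had 3 lower and 1 higher of 5 (median -1.80, or -2.86 with TDGF1 at its bound of 3 counts). This median ranged from -3.27 with a pseudocount of 1 to -0.40 without the low filter. SALL4 was at 18.4 against 186 CPM, DPPA4 at 2.43 against 48.9 and TDGF1 at 0 against 12.4, whereas L1TD1 was at 51.4 against 20.8 and POU5F1 at 23.8 against 16.4 (ratio 1.45, 0.936 to 2.25). Activin and nodal target genes, addressed by a factor that both media contained, had 4 lower and 1 higher of 7 (median -1.04, or -0.25 with the mean of per-cell CPM). SMAD7 and LEFTY2 were among the lower ones, and FST was 6.41-fold higher (5.39 to 7.65).

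**Figure D3:**
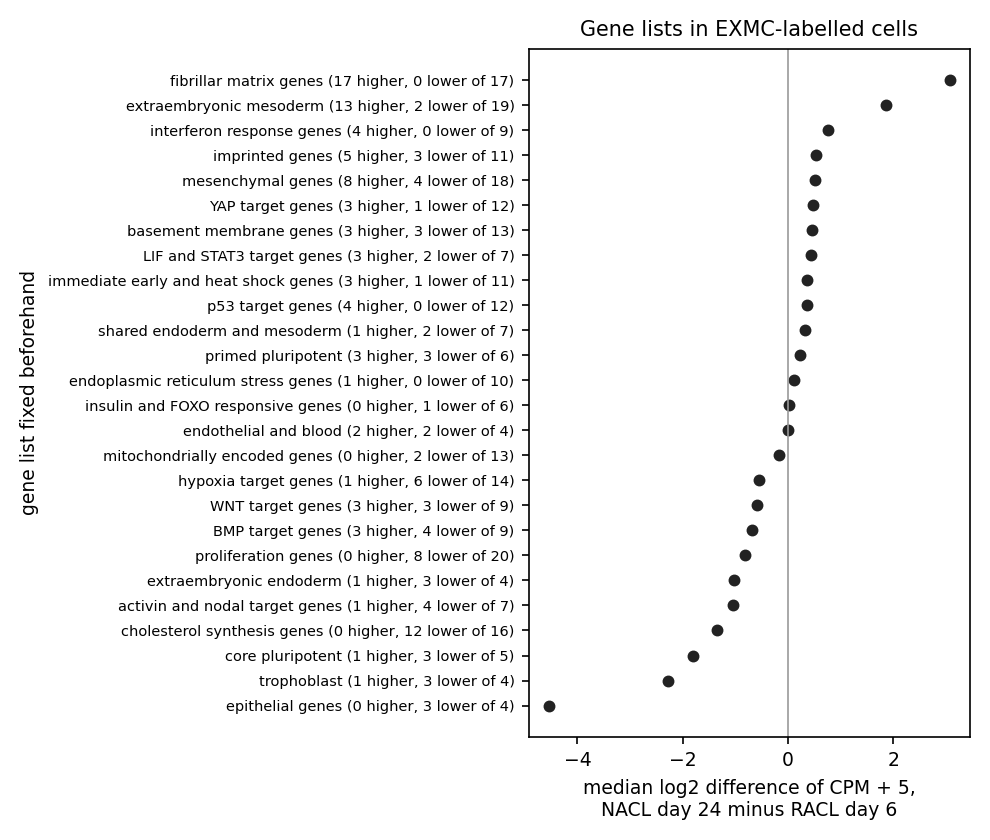
Median log2 difference of CPM + 5 between EXMC cells at day 24 and day 6 (horizontal axis) for each fixed list with at least 4 measured members (vertical axis, with the number of members higher and lower by the size rule). Fibrillar matrix genes had a median of 3.08 over 17 members. The median of -4.54 for epithelial genes rests on 4 members above the low filter.

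WNT target genes had 3 higher and 3 lower of 9 (median -0.58), BMP target genes 3 higher and 4 lower of 9 (-0.67), and YAP target genes 3 higher and 1 lower of 12 (0.48). LIF and STAT3 target genes had 3 higher and 2 lower of 7 (median 0.45, mean -0.01). The list shared by endoderm and mesoderm had 1 higher and 2 lower of 7 (median 0.33, mean -0.07), with GATA4 at 10.7 against 64.1 CPM and GATA6 at 24.3 against 61.7. p53 target genes had 4 higher and 0 lower of 12 (0.36), among them CDKN1A at 4.54-fold (3.73 to 5.55). Immediate early and heat shock genes had 3 higher and 1 lower of 11 (0.37), endoplasmic reticulum stress genes 1 higher of 10 (0.11), and insulin and FOXO responsive genes 1 lower of 6 (0.03, mean -0.17, with a median of the other sign under TMM scaling, DESeq2 scaling and totals without mitochondrial and ribosomal protein genes). Mitochondrially encoded genes had 2 lower of 13 (-0.18). Marker lists of other lineages had few measured members: 4 for endoderm (1 higher, 3 lower), 4 for trophoblast (1 higher, 3 lower), 6 for primed pluripotency (3 higher, 3 lower), 4 for endothelium and blood (2 higher, 2 lower) and 2 for amnion (1 lower). Naive pluripotency, primitive streak and neuroectoderm each had 1 measured member, KLF5 (lower), LHX1 (lower) and TUBB3 (neither), and secreted plasma proteins had 2, APOC1 (lower) and APOE (neither). The median of all 9512 measured genes was -0.03. With 1 library per condition, none of these differences could be set against the spread between cultures, and medium, days in culture and library could not be separated.

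Within the RACL library, EXMC cells were compared with PrE cells to describe what each label held. The labels were made from the same expression values, so the lists describe the labels and are no independent finding. EXMC cells had more matrix and mesoderm transcripts: COL3A1 was at 806 against 1.46 CPM, COL6A3 at 619 against 4.87 and NID2 at 250.5 against 2.43. Mesoderm markers were higher in 14 of 16 measured members (median log2 difference 1.99, or 2.37 with HGF at its bound), and HAND1 was at 162 against 296 CPM. Endoderm markers were lower in EXMC in 11 of 13 (median -2.62). In PrE cells CER1 was at 1449 CPM (1398 to 1502), NODAL at 349.6, APOA1 at 132, SOX17 at 113 (99.4 to 129) and OTX2 at 110 (95.7 to 125), against 11.2, 7.61, 6.41, 6.41 and 3.21 CPM in EXMC cells. These levels were uneven within the label. In the 25 PrE cells with a UMI of SOX17 or FOXA2, a split chosen after the data were seen, CER1 was at 2550 CPM, APOA1 at 262 and OTX2 at 205, against 412, 10.4 and 19.9 in the other 30. GATA6 was at 332 CPM in PrE and 61.7 in EXMC cells, against 1.51 in intermediate 1.

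PrE cells also carried transcripts of the primitive streak and of pluripotent cells. All 7 measured members of the streak list were lower in EXMC than in PrE cells (median -4.04). MIXL1 was at 770.4 CPM in PrE (733 to 809), LHX1 at 425, EOMES at 169.95 and MESP1, an early mesoderm factor, at 135. Intermediate 1 cells had 133 CPM of MIXL1 and 0.603 of LHX1. Between PrE cells with and without SOX17 or FOXA2, LHX1 was at 720 against 147 CPM, EOMES at 291 against 55.8, MESP1 at 84.3 against 183 and POU5F1 at 220 against 594. Core pluripotency genes were lower in EXMC in 8 of 9 (median -3.22) and naive ones in 6 of 7 (median -3.13). POU5F1 was at 412 CPM in PrE (385 to 441), 16.4 in EXMC and 1317 in intermediate 1, and L1TD1 at 1114, 20.8 and 1759 CPM. Over the alternatives the medians ranged from -3.95 to -2.13 for endoderm, 1.67 to 2.89 for mesoderm, -5.67 to -3.95 for streak, -4.20 to -2.46 for core and -4.31 to -1.56 for naive markers.

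**Figure D4:**
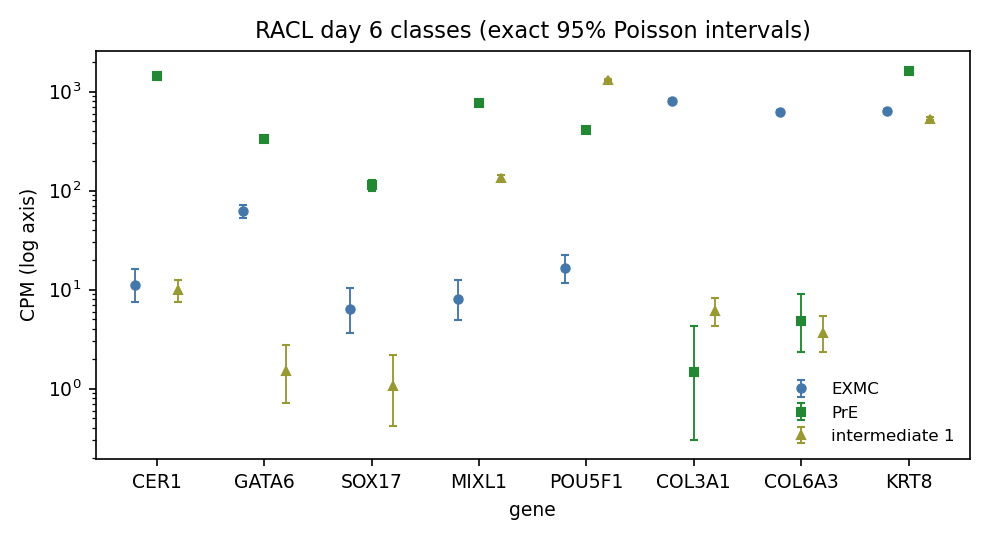
Levels of 8 genes (horizontal axis) in CPM on a log axis (vertical axis) in EXMC, PrE and intermediate 1 cells of the RACL library, with exact 95% Poisson intervals. POU5F1 in PrE (412 CPM) lay between EXMC (16.4 CPM) and intermediate 1 (1317 CPM).

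Other lists separated the RACL classes as well. Fibrillar matrix genes were higher in EXMC in 9 of 12 (median 1.95) and epithelial genes lower in 8 of 10 (median -1.71), with EPCAM at 2.40 against 104 CPM. Activin and nodal target genes were lower in EXMC in 10 and higher in 1 of 13 (median -4.04), LEFTY1 being at 2.81 against 529.8 CPM. Mesenchymal genes were higher in 7 of 14 (median 1.02), with ACTA2 at 202 against 0.974 CPM, and this median fell below 1 under 3 alternatives. Cholesterol synthesis and proliferation genes differed little, with 1 of 16 and 0 of 20 members past the size rule. Of the shared markers, VIM and BMP4 were higher and GATA6 and PDGFRA lower in EXMC (median -0.40).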

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

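The tests of feeder cells, free RNA, doublets, several kinds of cell, shallow sampling and of medium and handling were chosen after the results were seen, and those of scaling and of cell fragments before. The lists of syncytiotrophoblast and genome activation genes were also chosen after the data were seen.

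Signals appeared in barcodes outside the comparisons of EXMC and PrE cells. CGA, the alpha subunit of chorionic gonadotropin, had 2274 UMIs in the RACL intermediate 3 barcodes. H3Y1, a histone variant gene, had 665 UMIs in the RACL intermediate 2 cells. Fibrillar matrix genes had 60 UMIs in the 10 NACL intermediate 3 barcodes.

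The fibrillar matrix genes were higher in day 24 EXMC cells. Mouse feeder cells counted as human would lack human mitochondrial transcripts, but the 10th percentile over these cells of the mitochondrially encoded share was 2.85%. That share cannot show feeder RNA in droplets that also held a human cell. Free RNA of the NACL library would reach the 10 shallow barcodes as strongly as the cells. The level there was 0.359 times that of EXMC cells (0.274 to 0.462). Over the 10 barcodes the share of these genes ran from 0 to 3.15%, against a median of 2.98% in EXMC cells. The barcodes are a class named by the authors, and empty droplets were not examined, so this comparison cannot decide about free RNA. The annotation names those barcodes RACL.intermediate.3, but LUM was found in 6 of them, against 0 of the 252 intermediate 3 barcodes of the RACL library. DCN was found in 4 of the NACL barcodes and in 2 of the 252. For the NACL barcodes without LUM, the library of origin remains undecided. With TMM scaling the list median was 3.04, so a few abundant genes distorting the totals do not account for it. Medium, days in culture and library handling cannot be told apart, since each condition had 1 library, and a biological difference between the cultures stays open on the same ground.

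Pluripotency and streak transcripts were found in cells labelled PrE. Free RNA would give PrE and EXMC cells a like POU5F1 level, but PrE cells had 25.1 times that of EXMC cells (18.3 to 35.2). Doublets of pluripotent and SOX17-expressing cells cannot be told apart: SOX17 in the POU5F1-richer cells was 0.464 times that in the rest (0.349 to 0.611), an interval that includes the ratio set for doublets. The test of several kinds of cell under the label did not decide by the rule set for it. It counted SOX17 or FOXA2 with any UMI (25 cells) and MESP1 with 2 or more UMIs (19 cells). Both occurred together in 4 of 55 cells, against 8.64 expected if independent. The interval of the share (2.02 to 17.6%) includes the expected 15.7%. That interval does not hold the 25 and 19 cells fixed, so it is wide for this question. Neither marker was counted in 15 cells. Of the 5 marker pairs computed, the MESP1 pair was the test, and each pair counted its second gene only at 2 or more UMIs. TBXT (21 such cells) overlapped with SOX17 or FOXA2 in 3 cells against 9.55 expected. Its interval (1.14 to 15.1%) lay below the expected 17.4%. HAND1 (25 such cells) overlapped in 8 against 11.4. With any UMI, TBXT and HAND1 were each found in 32 PrE cells, and overlaps at that threshold were not computed. SOX17 overlapped with GATA6 in 23 against 18.8 and with CER1 in 23 against 20.9. A further split of the label was computed after these and not used as the test. In cells with SOX17 or FOXA2, 3 of 16 pluripotency and streak members were higher and 8 lower by the size rule, so levels were uneven within the label.

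Intermediate 3 barcodes of the RACL library had few UMIs of MALAT1, a nuclear RNA. No MALAT1 UMI was found in 61.9% of the 252 barcodes (55.6 to 67.9), against 10.4% of intermediate 1 cells thinned to the same depths. This argues against shallow sampling of whole intermediate 1 cells. Cells of other classes were not thinned for this comparison, so shallow whole cells of another kind stay open. Barcodes with under 1% mitochondrial UMIs had 0.237 times the MALAT1 level of the others (0.200 to 0.281), so fragments that lack nucleus and mitochondria are a candidate source. The median mitochondrial share was 0.296% in intermediate 3 and 9.26% in intermediate 1. No biological explanation was tested.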

How the results depend on the processing

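Alternatives limited to at least 10000 UMIs, or to PrE cells with SOX17 or FOXA2, were chosen after seeing the data. No paired analysis was possible because each condition had 1 library. Comparisons of endoderm between libraries, and of rebuilt EXMC with rebuilt endoderm, were not run, because the NACL library had 0 endoderm cells and no rebuilt RACL cluster was named endoderm-like. Removal of doublet calls left the RACL cells as they were, and the 0 PrE cells of the NACL library stay 0 under any cell filter, so values fixed in this way are not counted. Of 503 list medians under alternatives, 461 kept their direction and side of a 1 log2 threshold, 27 changed sign without reaching it (from at most 0.37 in size, the largest change being primed pluripotency in the EXMC comparison, 0.24 to -0.89 with per-cell CPM) and 15 crossed it with the same sign. Of 11 shares, 3 stayed inside the main counting interval. The 240 values of the 24 named EXMC genes kept direction and stayed past 1 log2, which their choice by largest difference nearly fixed beforehand. The smallest was LIX1 at -3.25 with per-cell CPM (main -4.27); folds of MGP, ACTC1, APLNR and AHR also moved by over 1.5 times, within their counting intervals. The fibrillar median ranged from 2.82 to 3.39.

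The shares moved with the cell filter. With at least 1000 genes and under 20% mitochondrial, EXMC was 16.3% of RACL and 100% of NACL and PrE 14.0% of RACL; with at least 0.5 times the library's median UMIs they were 18.4%, 100% and 16.0%, both because shallow barcodes were left out. With rebuilt clusters, NACL EXMC was 100% and RACL PrE 0%. Of the 55 PrE cells, 33 fell in a cluster named primitive streak-like, 13 in core pluripotent-like, 6 in naive pluripotent-like and 3 in mesoderm-like clusters. A cluster took only its best-scoring name, and the top genes of the streak-like cluster included CER1 and SOX17. Thinning to 10000 UMIs also leaves out cells below that depth. In the cells kept, those with a UMI went from 23 to 14 of 52 for SOX17 and 26 to 15 for MESP1 in PrE, and from 21 to 7 of 60 for POU5F1 in RACL EXMC (14.9% of all 67 at 2 or more UMIs). LUM in NACL EXMC went from 98.5 to 100% through the cells left out alone.

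In the EXMC comparison, the mean of per-cell CPM gave -1.10 for proliferation genes, -0.25 for activin and nodal targets and -0.37 for endoderm. Without a low filter the medians were -0.51 for epithelial, -0.40 for core pluripotent, -0.85 for activin and nodal, -0.71 for endoderm and -0.16 for trophoblast genes, and without doublet calls -0.93 for activin and nodal genes. Lower members went from 8 to 14 of 20 for proliferation with per-cell CPM (by fold alone), and without a low filter from 3 to 5 for epithelial and for WNT target genes, 4 to 8 for activin and nodal and 3 to 9 for endoderm genes (5 with totals lacking mitochondrial and ribosomal protein genes). Between RACL EXMC and PrE, the mesenchymal median was 0.73 with per-cell CPM, 0.62 without a low filter and 0.68 with the restricted PrE cells, WNT targets (main -0.94) were at -1.24 with per-cell CPM and -1.07 with a pseudocount of 1, and secreted plasma proteins (main -2.85) at -0.13 without a low filter. There, lower imprinted genes went from 6 to 3 with per-cell CPM and higher basement membrane genes from 6 to 3 with the restricted PrE cells. The cause was not tested beyond the low filter, which adds members near 0. In this comparison the median of all genes was -0.09, and 0.04 with TMM scaling and 0.07 with DESeq2 factors.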

Other observations

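The intermediate classes of the RACL library differed among themselves, by levels that carry counting error only. Intermediate 2 cells, compared with intermediate 1, had higher p53 target genes in 8 of 11 members (median log2 difference 1.20), among them CDKN1A at 329 against 27.3 CPM and GDF15 at 377 against 37.6. Immediate early and heat shock genes were higher in 10 of 12 (1.70), with ATF3 at 183 against 19.8 CPM. Trophoblast markers were higher in 7 of 8 (2.25), KRT7 being at 89.6 against 2.56 CPM and GATA3 at 74.8 against 4.37, and naive markers in 7 of 11 (1.28). All 13 mitochondrially encoded genes were lower (-1.76), and 35 of the 63 cells had under 1% mitochondrial UMIs. POU5F1 was at 887 CPM in intermediate 2 and 1317 in intermediate 1.

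Small sets of barcodes carried transcripts of other states. CGA-rich barcodes, with at least 10 UMIs of CGA, numbered 17, all in intermediate 3 (2.87% of RACL cells, 1.68 to 4.55), with a median of 830 UMIs and CGA at a median of 7.87% of them. PGF was found in 12 of these, CYP19A1, the placental aromatase, in 8, INSL4 in 4 and LEP in 3, and each of the 4 in 1 of the other 235 intermediate 3 barcodes (median 904 UMIs). The rest of the RACL library held 131 PGF UMIs, against 105 in the 17. The 17 barcodes held 2186 of the 2356 CGA UMIs of the library, and the NACL library held 0. They were picked by CGA, so that count is no independent support. Their median mitochondrial share was 0.361%, and MALAT1 was found in 6 of the 17. Whether they were whole cells or fragments was not tested. CGB3, CGB5 and CGB8 share reads as near-identical copies and had 18, 4 and 4 UMIs in the 17 barcodes. A set of 14 cells, 13 of them intermediate 2, had at least 2 of 6 genes of embryonic genome activation. They were picked by these genes, so the counts are no independent support. They held 603 UMIs of H3Y1, 58 of TPRX1, 19 of TRIM43, 11 of LEUTX and 4 of ZSCAN4, and the NACL library had 0 UMIs of each. Of other genes on that list, DUXA had 0 UMIs and DUXB 1 in them, and KHDC1L had 1501, against 3358 in RACL cells outside intermediate 2.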
